A study of Arabidopsis thaliana with 4 samples.

How the data were processed

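DNA affinity purification sequencing (DAP-seq) was used to find where MYB67, an R2R3 MYB transcription factor of Arabidopsis thaliana, binds naked genomic DNA. In this assay a tagged transcription factor is made in a cell-free extract, held on beads and mixed with a sheared genomic DNA library, and the DNA that stays on the beads is sequenced. Binding is measured in vitro, on DNA that carries no chromatin, and no gene expression is measured. Per the labels' protocols, MYB67 carried a Halo tag, was produced in wheat germ extract, and was incubated with adapter-ligated genomic DNA of the accession Col-0. The protocol states that this DNA came from leaf, whereas the tissue label of the libraries reads root. The labels list 4 libraries, 2 with MYB67 and 2 with an empty vector that gives the Halo tag alone.

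The 4 deposited files that were used describe 1 set of MYB67 peaks, and none of their columns belongs to a single library. The submitters' processing notes name FastQC, Trimmomatic 0.39, STAR 2.7.10a, Picard 2.27.1, MACS3 3.0.0a7, HOMER, bedtools and the genome build TAIR10, without their order or settings. How the 2 MYB67 libraries were combined, and how the empty-vector libraries entered peak calling, is not given in the sources used here. Each peak in the authors' peak list carries a fold enrichment, a ratio of signal to the background that the peak caller modelled, and a −log10 q. The authors' deposited gene table repeats each fold and gives the peak q-value itself, together with at most 1 gene per peak and a mark for a motif site. A separate deposited list gives the q-value of each motif site found by FIMO, kept up to 0.05 per the file name. Its coordinates are those of the whole peak and not of the site, so sites could be counted per peak but not placed within it. Of its 12446 entries 311 repeat another of the same peak and q in full, and each was counted as a site. The authors' motif matrix, in HOMER's format, gives the fraction of each base at each position, and its header gives the shares of target and background sequences with the motif. A peak's fold and q are the authors' values for the peak, carry no replicate error, and were compared only among peaks of this list.

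Such processing bears on the values in several ways. A fold is set by the background estimate as well as by binding, so regions with a high read depth can pass the q threshold at a low fold. The number of peaks depends on the sequencing depth, and the depth of the libraries is unknown here. Wider peaks hold more sequence in which FIMO can find a site. The rule by which the authors joined peaks to genes is not given in the sources used here. Intervals on shares of peaks or genes are 95% Wilson intervals and cover counting error only.

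Gene symbols, neighbouring genes and gene lengths were taken from a RefSeq table of the assembly TAIR10.1, which holds 27444 nuclear protein-coding genes. All 4030 nuclear genes to which a peak was assigned matched it by locus identifier. Printed positions are those of the peak list in TAIR10, counted from 1. The table has no strand and its assembly differs by name from that of the peaks, so peaks were not placed in exons, introns, untranslated regions or promoters. No genome sequence was used.

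Lists of genes for 9 processes and name patterns for gene families were fixed before the data were examined. For each list, and each family with at least 5 members, the genes with an assigned peak were compared with all other nuclear protein-coding genes by Fisher's exact test, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 9 lists and, separately, over the 9 families that could be built from gene symbols. LACS2, MYB36, MYB84 and PER64 each stand in 2 lists, so the lists are not fully independent. Differences in median fold were tested with 100000 permutations, two-sided, and relations across peaks were described with Spearman's rho and Pearson's r with permutation p-values, of which 1e-05 is the smallest possible. Peaks and genes are not independent replicates, and these tests measure no spread between libraries. The threshold on adjusted p was 0.05. The rule for named genes covered every gene of the suberin biosynthesis list and of the suberin regulator list with a peak, up to 4 genes per other list with the highest fold, the 10 genes with the highest fold over all, and MYB67. A gene's value is that of its strongest peak. Other genes are named where stated, and were chosen after their values were seen.

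Alternatives set before the data were examined were the peaks in the upper 50% by fold, peaks with a −log10 q of at least 10, peaks with a FIMO site, −log10 q as the measure of strength, and corrections for peak width. FIMO sites with a q of at most 0.01, nuclear peaks alone, family members matched by synonym, and a corrected set of fatty acyl-CoA reductases were added after seeing the data. The same holds for the tests of fold by list, the ABCG transporters outside the lists and the scan of all numbered gene symbols. The planned scan of control regions, distances of sites to summits, peak locations relative to genes, other rules of gene assignment and matching on upstream length were not run, because they need sequence, site positions or strand. Families defined by product text were not run either, since the table holds no such text.

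The tests were first tested on simulated data. Over the same 27444 genes, a list of 21 genes with no effect passed an unadjusted 0.05 in 1.33% of 300 runs, and one whose members had a peak 50% of the time passed in 96% of them. For a list of 10 genes the shares were 3.67% and 80.3%. The permutation test of medians, over the 5390 peaks, passed in 7.5% of 40 runs with no shift in fold and in 100% with a shift of 1, and the test of Spearman's rho passed in 2.5% of 40 runs with no relation. The runs of medians drew sets of 202 peaks, so sets as small as the genes of a list were not simulated. In the runs of lists each gene outside the list had the same chance of a peak. Effects of gene length or spacing were therefore not simulated. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.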

Results

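The series concerns the root of Arabidopsis thaliana and the part MYB67 plays in the phellem, the suberised outer layer of the periderm that replaces the epidermis as the root thickens. Its DAP-seq arm asked which genes MYB67 binds directly. The data comprised 2 MYB67 libraries and 2 empty-vector libraries, deposited as 1 list of MYB67 peaks with the motif found in them and the gene assigned to each peak. No value belonged to a single library, so depth per library is unknown and no replicate error could be given for any peak.

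MYB67 peaks were spread over all 5 nuclear chromosomes. The list held 5390 peaks, of which 5338 were nuclear, 51 mitochondrial and 1 plastid. Chromosome 1 carried 1349 peaks, chromosome 2 901, chromosome 3 1009, chromosome 4 821 and chromosome 5 1258, which is 43.1 to 46.7 peaks per Mb of the span between the first and last peak. Density was lower in some regions of each chromosome, as the plot of peaks along the chromosomes shows. Among 116 complete bins of 1 Mb the median was 46 peaks. The lowest bins held 9 peaks each, at 14 to 15 Mb of chromosome 1 and 3 to 4 Mb of chromosome 4, and the highest held 79, at 12 to 13 Mb of chromosome 2. On chromosome 5 the lowest bin, at 11 to 12 Mb, held 10 peaks. The lowest bin of chromosome 2, at 5 to 6 Mb, held 21, and that of chromosome 3, at 13 to 14 Mb, held 19. The median fold enrichment was 4.38 (quartiles 3.74 and 5.57, range 1.28 to 23.2), the median −log10 q 8.21 and the median width 257 bp. Restricting the list to a −log10 q of at least 10 left 2162 peaks.

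**Figure D1:**
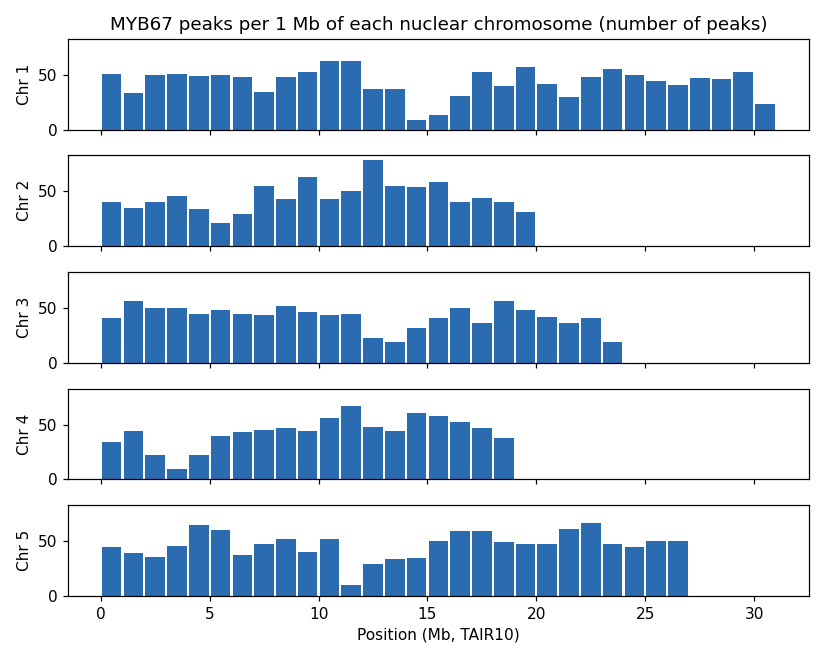
Number of MYB67 peaks in consecutive bins of 1 Mb along the 5 nuclear chromosomes (x axis, position in Mb of TAIR10; y axis, number of peaks per bin). Bars show a median of 46 peaks per complete bin. Lows are 9 on chromosomes 1 and 4, 10 on chromosome 5, 19 on chromosome 3 and 21 on chromosome 2. The last bar of each chromosome covers an incomplete bin.

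The authors assigned 4464 peaks, 82.8% of the list (95% interval 81.8 to 83.8%), to a gene. These were 4058 genes, 4030 of them nuclear, or 14.7% of nuclear protein-coding genes. A single peak was assigned to 3665 nuclear genes, 2 peaks to 332, 3 peaks to 30 and 4 peaks to 3. The highest fold at an assigned gene, 21.6, lay at CB5-B (AT2G32720; chromosome 2, 13878431 to 13879063), which encodes a cytochrome b5 isoform. It was followed by CWLP (AT3G22120; chromosome 3, 7795481 to 7796246), a gene for a cell wall linker protein, at 19.9, and by the loci AT3G23300 at 19.8, AT1G47480 at 19.7 and AT4G21630 at 18.3. The potassium channel gene KT1 (AT2G26650, also called AKT1) had a fold of 18.2, as did C4H, the cytochrome P450 gene of the second step of phenylpropanoid synthesis. IQD22 (AT4G23060) reached 17.7, NAC007 (AT1G12260, also called VND4, a regulator of xylem vessel formation) 17.3 and AT5G62210 17.0.

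The motif of the MYB67 peaks was rich in A and C. Its consensus, TCYACCTAMC, had 10 positions and 11.9 bits of information, with 6 positions above 1 bit. In the matrix, position 4 was A at 99.7%, position 6 was C at 99.7% and position 8 was A at 99.5%, as the plot of base frequencies shows. At positions 4 and 6 each other base stood at 0.1%, the lowest value in the matrix, so these are not counts of sites with another base. Position 5 was C in 86.3%, and position 7 was T in 68.9% and A in 30.4%. Position 9 was split between C at 53.2% and A at 46.1%. Per the header of the authors' deposited motif, its closest known match was the motif of MYB111, a regulator of flavonol synthesis, with a similarity of 0.963. The same header placed the motif in 3885 target sequences, 72.78% of them, and in 9.15% of background sequences, a ratio of 7.95 with a log10 p of -2740. The target share equals 3885 of the 5338 nuclear peaks, and the motif was found in these peaks. This ratio and p are therefore no independent test of the motif.

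**Figure D2:**
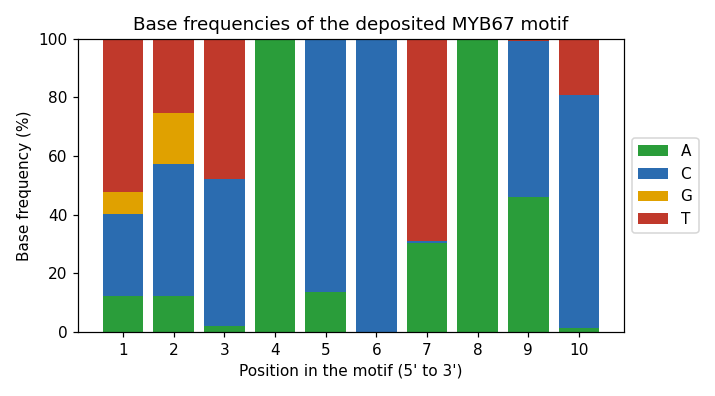
Base frequencies of the deposited MYB67 motif (x axis, position from the 5′ end; y axis, percent of each base, stacked, 1 colour per base). Positions 4, 6 and 8 are close to invariant, with A, C and A at 99.7%, 99.7% and 99.5%.

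FIMO, a scan with a threshold of its own, marked the motif in most peaks. At a q of up to 0.05, 5188 of 5390 peaks held at least 1 site (96.25%, 95% interval 95.7 to 96.7%), and 202 held none. A peak held 2.31 sites on average and 25 at most. At a q of up to 0.01, chosen after the data were seen, 2549 peaks held a site (47.3%). No control regions were scanned here, so these shares have no background of their own. The motif had been found in these same peaks, so the shares are no independent test of it either.

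Peaks with a FIMO site were stronger than peaks without one. The median fold was 4.38 in the 5188 peaks with a site and 3.84 in the 202 without, a difference of 0.54 (permutation test, two-sided, p = 4e-05). Peaks with a site were also wider, with a median of 258 bp against 229 bp. Permuting within 10 bins of peak width, a difference of 0.282 was expected from width, and 0.259 was left beyond it (permutation p = 0.00034).

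The fold also rose with the number of sites, from a median of 3.84 with none and 4.15 with 1 site to 5.12 with 4 sites and 6.53 with 6 or more, as the plot of fold by number of sites shows. Across peaks, Spearman's rho was 0.243 and Pearson's r 0.324 (permutation p = 1e-05 for each, the smallest possible; adjusted p = 1.12e-05 over 9 relations). Without the 2 peaks farthest from the median number of sites, r was 0.310. Per 100 bp of peak the relation was lost in ranks (rho 0.0131, permutation p = 0.334; r 0.0537, permutation p = 5e-05), and peak width itself rose with fold (rho 0.596, r 0.532, permutation p = 1e-05 for each).

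**Figure D3:**
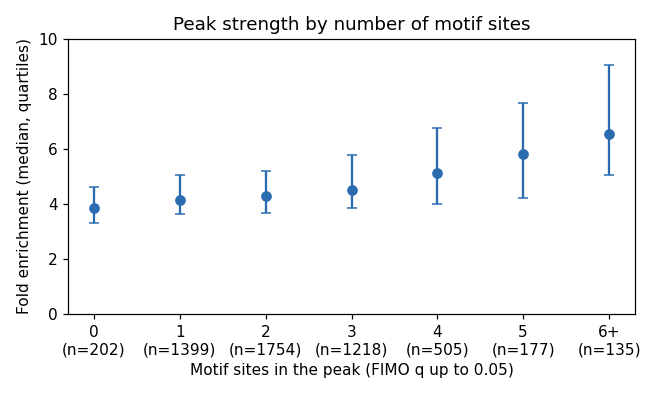
Fold enrichment of MYB67 peaks (y axis, median as points with quartiles as bars) by number of FIMO sites in the peak (x axis, with the number of peaks in each class). The median rises from 3.84 in peaks with no site to 6.53 in peaks with 6 or more.

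Genes of the phenylpropanoid and lignin pathway carried MYB67 peaks most often among the 9 lists. Of its 24 genes 13 had a peak (54.2%), against 14.6% of other genes (odds ratio 6.88, 95% interval 2.84 to 17.0, Fisher's exact test, adjusted p = 6.58e-05). At a −log10 q of at least 10 the odds ratio was 11.1. C4H (AT2G30490; chromosome 2, 12995681 to 12996173) had the seventh highest fold of all assigned genes, 18.2, in a peak with 9 sites. CSE (AT1G52760; chromosome 1, 19650185 to 19650798), which releases caffeate for lignin synthesis, had a fold of 15.6 and 11 sites. The ligase gene 4CL1 (AT1G51680; chromosome 1, 19162435 to 19162838) had 12.3, and PAL4 (AT3G10340; chromosome 3, 3202733 to 3203065), one of the genes for the entry enzyme of the pathway, had 11.5. The other 9 were CYP98A3, PAL2, 4CL5, HCT, PAL1, CCR1, CAD4, COMT1 and 4CL3. No peak was assigned to PAL3, 4CL2, CCoAOMT1, CCR2, CYP84A1 or CAD5. None was assigned to any laccase or peroxidase gene of the list either, namely LAC4, LAC11, LAC17, PER64 and PER72. The strongest peaks of the 13 genes had a median fold of 7.68, against 4.45 at other genes with a peak, and 8 of them lay above the 75th percentile of such genes (difference 3.23, permutation test, two-sided, adjusted p = 0.00063 over 9 lists; chosen after the data were seen).

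Genes of suberin biosynthesis and export had a peak in 10 of 21 cases (47.6%, odds ratio 5.29, 95% interval 2.01 to 13.7, Fisher's exact test, adjusted p = 0.00103). The highest fold, 6.47, was at FACT (AT5G63560; chromosome 5, 25448485 to 25449088), which makes alkyl caffeates. The ABC transporters ABCG1 (AT2G39350; chromosome 2, 16432584 to 16432932), ABCG6 (AT5G13580; chromosome 5, 4373066 to 4373340) and ABCG2 (AT2G37360; chromosome 2, 15675957 to 15676225), which export suberin precursors, had folds of 5.67, 4.96 and 4.54. The lipid transfer protein gene LTPG15 (AT2G48130) had 5.12 and the acyl-CoA synthetase gene LACS2 (AT1G49430) 5.07. The fatty acyl-CoA reductase genes FAR5 (AT3G44550) and FAR1 (AT5G22500) had 4.83 and 3.31, the hydroxylase gene CYP86B1 (AT5G23190) 4.38 and the acyltransferase gene GPAT7 (AT5G06090) 4.25. The 11 without an assigned peak included GPAT5, CYP86A1, ASFT, FAR4, KCS2 and KCS20, which act in the synthesis of suberin monomers. The median fold of the 10 genes, 4.90, was not separable from that of other genes with a peak (difference 0.446, permutation adjusted p = 0.630). With FIMO sites of a q up to 0.01 alone, 4 of the 21 genes had a peak and the call was lost (odds ratio 2.85, Fisher's exact test, adjusted p = 0.160).

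The MYB and NAC regulators of suberin had a peak in 3 of 17 cases (odds ratio 1.25, 95% interval 0.229 to 4.46, Fisher's exact test, adjusted p = 0.729). These were MYB84 (AT3G49690; chromosome 3, 18427207 to 18427457) with a fold of 5.27, NAC038 (AT2G24430; chromosome 2, 10386989 to 10387272) with 4.56 and MYB36 (AT5G57620; chromosome 5, 23333136 to 23333399) with 3.80. MYB67 itself had no assigned peak.

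Flavonoid genes had a peak in 11 of 22 cases (50%, odds ratio 5.82, 95% interval 2.29 to 14.8, Fisher's exact test, adjusted p = 0.000444). DFR (AT5G42800; chromosome 5, 17165940 to 17166340), an enzyme of anthocyanin and proanthocyanidin synthesis, had a fold of 9.09. AHA10 (AT1G17260), a proton pump of seed coat vacuoles, had 6.52, CHIL (AT5G05270) 6.28, and MYB123 (AT5G35550), the regulator also known as TT2, 5.11.

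Cutin and wax genes had a peak in 10 of 30 cases (33.3%, odds ratio 2.91, 95% interval 1.22 to 6.52, Fisher's exact test, adjusted p = 0.0187), and at a −log10 q of at least 10 the odds ratio was 4.72. CER3 (AT5G57800), needed for alkane formation in wax, had a fold of 9.46, GPAT8 (AT4G00400) 8.03, HTH (AT1G72970) 6.85 and CYP86A8 (AT2G45970) 6.70. With sites of a q up to 0.01 alone, 4 genes had a peak and the call was lost (odds ratio 1.87, Fisher's exact test, adjusted p = 0.512). Xylem secondary wall genes had a peak in 7 of 19 cases (36.8%, odds ratio 3.39, 95% interval 1.13 to 9.35, Fisher's exact test, adjusted p = 0.0262). IRX9 (AT2G37090), which acts in xylan synthesis, had a fold of 9.77, the protease gene XCP2 (AT1G20850) 8.25, and the lignin regulators MYB85 (AT4G22680) and MYB63 (AT1G79180) 6.85 and 5.97. Among peaks in the upper 50% by fold this call was lost (odds ratio 3.15, Fisher's exact test, adjusted p = 0.101), whereas with sites of a q up to 0.01 alone it held at 6 of 19 genes (odds ratio 5.60, adjusted p = 0.00668).

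The remaining lists did not pass the threshold. Casparian strip genes had a peak in 3 of 13 cases (odds ratio 1.74, Fisher's exact test, adjusted p = 0.544), namely CASP5 (AT5G15290) with a fold of 5.66, MYB36 and ESB1 (AT2G28670) with 2.88. Cambium and phellogen regulators had one in 3 of 10 (odds ratio 2.49, Fisher's exact test, adjusted p = 0.257), namely MYB84, HB8 (AT4G32880) with 4.38 and LBD4 (AT1G31320) with 3.93. Photosynthesis genes, a list not chosen for MYB67, had one in 2 of 23 (odds ratio 0.553, 95% interval 0.0628 to 2.26, Fisher's exact test, adjusted p = 0.635), namely LHCB2.1 (AT2G05100) with 8.88 and PSBO2 (AT3G50820) with 4.47. Intervals for these lists and for the suberin regulators are wide, and a share above that of other genes was not excluded for any of them. Odds ratios of the suberin regulators, Casparian strip and photosynthesis lists crossed 1 in other settings, and that of the cambium and phellogen list was 1.35 with sites of a q up to 0.01.

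**Figure D4:**
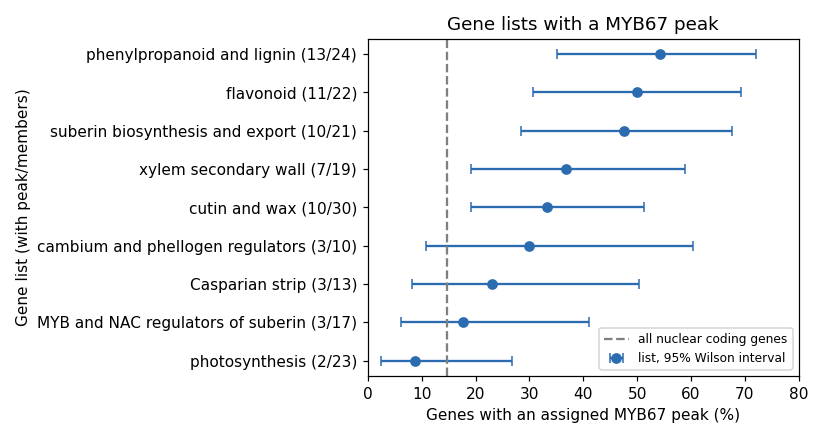
Share of each gene list with an assigned MYB67 peak (x axis, percent of genes; points with 95% Wilson intervals; y axis, list with genes with a peak over members), with all nuclear protein-coding genes as a dashed line at 14.7%. Shares run from 54.2% in phenylpropanoid and lignin genes to 8.70% in photosynthesis genes.

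**Figure D5:**
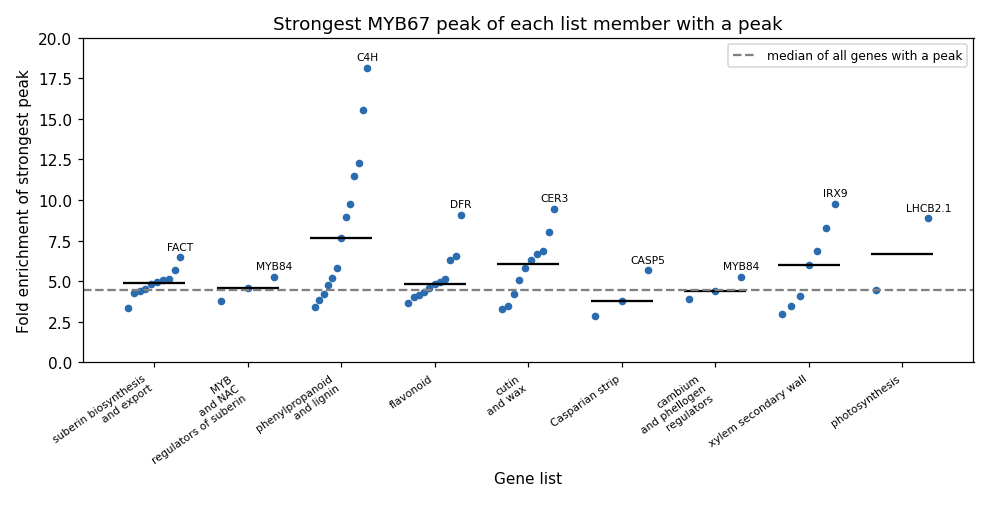
Fold enrichment of the strongest MYB67 peak (y axis) of each gene with a peak in the 9 lists (x axis). Each point is a gene, bars are list medians, the dashed line is the median of all genes with a peak, 4.46, and the gene with the highest fold of each list is named. Phenylpropanoid and lignin genes reach 18.2 at C4H with a median of 7.68.

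Among 9 gene families, ABCG transporters stood out, with a peak at 20 of 42 genes (47.6%, odds ratio 5.30, 95% interval 2.74 to 10.2, Fisher's exact test, adjusted p = 3.61e-06). The highest folds, named after their values were seen, were 7.02 at ABCG34, 6.81 at ABCG38 and 6.21 at ABCG28. Outside the lists, 16 of 35 ABCG genes had a peak (odds ratio 4.91, Fisher's exact test, p = 1.12e-05). These 16 are among the 20 genes above, so this is not a separate result. Gene length and peak-rich neighbourhoods were not tested for this family and stay open.

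WRKY factors had a peak at 18 of 67 genes (26.9%, odds ratio 2.14, 95% interval 1.17 to 3.74, Fisher's exact test, adjusted p = 0.0388), but the call was lost when only peaks with a FIMO site were counted (17 of 67, odds ratio 2.06, adjusted p = 0.0607). R2R3 MYB factors, the family of MYB67, had one at 22 of 115 genes (odds ratio 1.38, Fisher's exact test, adjusted p = 0.279) and NAC factors at 14 of 81 (odds ratio 1.21, adjusted p = 0.679). In the other settings the odds ratio of R2R3 MYB factors ran from 1.28 to 1.98 and passed in none. The highest was at a −log10 q of at least 10 (Fisher's exact test, adjusted p = 0.0643). The odds ratio of NAC factors turned to 0.969 at a site q up to 0.01. Laccases, a family with members that oxidise lignin monomers, had a peak at 5 of 14 genes (odds ratio 3.23, Fisher's exact test, adjusted p = 0.105). These were LAC2, LAC5, LAC8, LAC10 and LAC13, named after their values were seen. The laccases of the phenylpropanoid and lignin list, LAC4, LAC11 and LAC17, had none. GPAT acyltransferases had a peak at 3 of 9 (odds ratio 2.91, Fisher's exact test, adjusted p = 0.241), CYP86 and CYP94 hydroxylases at 3 of 16 (odds ratio 1.34, adjusted p = 0.810) and 3-ketoacyl-CoA synthases, which elongate fatty acids, at 3 of 21 (odds ratio 0.968, adjusted p = 1). Fatty acyl-CoA reductases had one at 4 of 10 genes (odds ratio 3.88, Fisher's exact test, adjusted p = 0.105). The symbol pattern had taken in 2 unrelated genes, a methionine synthase gene with a peak and a light signalling gene without one, and 3 of the remaining 8 had a peak (odds ratio 3.49, Fisher's exact test, adjusted p = 0.225). The odds ratios of these small families moved with the peaks counted. At a −log10 q of at least 10 laccases had 1 of 14 (odds ratio 1.19) and the 10 genes of the reductase pattern 3 (odds ratio 6.64), and at a site q up to 0.01 the values were 1 of 14 (odds ratio 0.932) and 1 of 10 (odds ratio 1.35), with 0 of 9 GPAT genes. The odds ratio of 3-ketoacyl-CoA synthases was 1.63 and 2.02 in these settings, in turn.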

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

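The tests of the mitochondrial peaks were chosen after these peaks had been seen. A total of 51 peaks lay on the mitochondrial chromosome, at 139 per Mb against 43.1 to 46.7 on the nuclear chromosomes, and were singled out as a signal outside the comparisons of genes. Their median fold was 3.18, and 46 of them (90.2%) held a FIMO site at the deposited q of up to 0.05, against 96.3% of nuclear peaks (Fisher's exact test, two-sided, p = 0.0410), while 12 (23.5%) held one at a q of up to 0.01, against 47.5% (p = 0.0006046). At a given −log10 q, 45 of 51, or 88.24%, lay below the median fold of the 20 nuclear peaks nearest in −log10 q. A greater depth of organelle DNA would give such low folds, but the plastid chromosome had only 1 peak, with a fold of 1.28, so this stays open as well. A window of chromosome 2 from 3.2 to 3.52 Mb, which lies where Arabidopsis carries a nuclear copy of mitochondrial DNA and whose bounds were set after seeing its peaks, held 28 peaks with a median fold of 3.13, and 89.29% of them lay below their nuclear counterparts, so reads shared between the copies may be part of both groups. Whether these peaks lack the motif is left open too, as most hold a site at the deposited threshold and no control regions were scanned, and no biological explanation was tested.

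The authors assigned no gene to 926 peaks, which the comparisons of genes therefore leave out. Their median fold was 4.51, against 4.38 in assigned peaks, and 40.0% of them held a FIMO site at a q of up to 0.01, against 48.8%. The highest folds of the whole list were among them, 23.2 on chromosome 1 at 12888099 to 12888600 with 6 sites, and 22.7 on chromosome 2 at 1728448 to 1728845 with 3 sites.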

How the results depend on the processing

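Settings with FIMO sites of a q up to 0.01, nuclear peaks alone and other family members were chosen after seeing the data. Of the 36 list results under alternatives, 33 stayed on their side of the threshold and 3 did not. With sites of a q up to 0.01 only 3 lists passed in place of 5, as the odds ratio of the suberin list fell to 2.853 and that of the cutin and wax list to 1.865. In the upper 50% of peaks by fold the xylem secondary wall list did not pass (3.151), while with sites of a q up to 0.01 its odds ratio was 5.603. At a −log10 q of at least 10 the phenylpropanoid and lignin list rose to 11.1 and the suberin list to 6.203. The cutin and wax list rose to 4.721 and the xylem secondary wall list to 4.131, while the flavonoid list fell to 4.558. Other sets, which passed in no setting, turned across an odds ratio of 1, namely photosynthesis (1.124) and Casparian strip (0.9834) in the upper 50%, the suberin regulators at a −log10 q of at least 10 (0.9664) and at a site q up to 0.01 (0.7569), and NAC factors (0.9689), laccases (0.9317) and GPAT acyltransferases (0) at a site q up to 0.01. 3-ketoacyl-CoA synthases turned from 0.9683 to between 1.006 and 2.02 in 4 settings. Fatty acyl-CoA reductases ranged from 1.346 to 6.636. Of the 46 family results 42 stayed on their side. ABCG transporters passed in each setting, and 1 family passed in place of 2 in 4 settings, since WRKY factors were lost in the upper 50% (1.602), at a −log10 q of at least 10 (2.407), with a FIMO site required (2.056) and with a site of a q up to 0.01 (1.645). Each of these settings counts fewer peaks, and whether that is the cause was not tested. The list held 2779 peaks in the upper 50%, ties at the median included, and 2162 at a −log10 q of at least 10. The share of peaks with a site was 97.55% and 97.96% in these, and 47.29% at a site q up to 0.01. The difference in fold with and without a site fell from 0.541 to 0.2591 beyond that expected from peak width, still past the threshold, and passed it with −log10 q as the measure, sites of a q up to 0.01 and nuclear peaks alone. It no longer passed at a −log10 q of at least 10 (0.3743, permutation p = 0.213) and passed in the upper 50% (0.5442), but these subsets are filtered on the strength compared and do not test the difference. The rank correlation of fold with sites was lost per 100 bp (rho 0.01312), while Pearson's r, 0.0537, still passed, and the cause was not tested beyond the rise of width with fold. No paired analysis was possible because no column belongs to a single library, and no replicate could be left out. Not run were the scan of control regions, other matrix thresholds, the region around the summit, distances of sites to summits, peak locations with their promoter lengths and peak points, other gene assignments, and matching on upstream length. With the depth of the libraries unknown, a gene without a peak is not shown to be unbound.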

Other observations

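The clusters, the scan of gene symbols and the tests between lists in this part were chosen after the data had been seen, as was the test of list strength; the tests on matched random sets and on neighbouring genes were set before their results were seen, the latter after a test on adjacent genes that all 5 lists had passed was set aside, since adjacent genes compete with the members for peaks assigned to 1 gene each. The peak with the most motif sites, 25, was assigned to AT4G22475 (chromosome 4, 11844605 to 11845446) and had a fold of 13.1. A further peak of 12 sites lay beside it at the same gene, and AT4G22505 (chromosome 4, 11851667 to 11852729) had 16 sites. CWLP had 19 sites, and AT3G22125 (chromosome 3, 7807443 to 7808012) 12. PAL2 had 13 sites in a peak of 959 bp. Among R2R3 MYB genes with a peak, the highest folds were 10.8 at MYB69, 9.02 at MYB32, 8.27 at MYB25 and 8.24 at MYB40.

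In a scan of 170 numbered series of gene symbols with at least 10 members, ABCG alone passed the adjusted threshold (Fisher's exact test, adjusted p = 6.82e-05), and 15 series had an unadjusted p under 0.05. The ABCG series is the family tested above, with the same 20 of 42 genes. Its result is the same test adjusted over more sets and adds no separate support. Next by unadjusted p, apart from WRKY factors, beta-galactosidases (BGAL) had a peak at 7 of 15 genes (Fisher's exact test, adjusted p = 0.270), the HDG series at 5 of 10 (adjusted p = 0.301) and the GH series at 9 of 26 (adjusted p = 0.301). The LCR series had one at 4 of 80 genes (odds ratio 0.305, Fisher's exact test, adjusted p = 0.301).

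Peaks were more frequent in 5 lists than in other genes, and 2 technical explanations were tested. Gene length was argued against, since 100% of 10000 random lists matched on gene length had fewer genes with a peak than the phenylpropanoid list, 99.99% than the flavonoid list, 99.89% than the suberin list, 98.33% than the cutin and wax list and 98.31% than the xylem secondary wall list. Peak-rich neighbourhoods were argued against for the phenylpropanoid and flavonoid lists by the genes 2 places away from the members. Of these, 14.6% and 13.6% had a peak (Fisher's exact test, p = 0.0007274 and 0.00256, adjusted p = 0.00364 and 0.0064 over 5 lists). For the suberin list the share was 21.4%, and the test did not pass after adjustment (Fisher's exact test, p = 0.04393, adjusted p = 0.0732). The rule set beforehand was an unadjusted p under 0.05, which the suberin list met. The adjustment lay outside that rule, and the more cautious reading is kept here. Peak-rich neighbourhoods stay open for suberin genes, cutin and wax genes (16.9%, Fisher's exact test, p = 0.1076) and xylem secondary wall genes (15.8%, p = 0.09866). Length of the upstream region, base composition and the frequency of MYB motifs in these promoters stay open.

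Phenylpropanoid and lignin genes with a peak had stronger peaks than other genes with a peak, by a difference in median fold of 3.23. The difference remained against 10000 random sets matched on the number of motif sites, counted up to 6 or more. Of these sets 99.46% had a lower median fold (5.41 on average, against 7.68), although they rose above the 4.45 of other genes. Matching on the q of the best site gave 99.95%. The strongest peaks of PAL1, C4H, CSE and PAL2 held 7, 9, 11 and 13 sites, above the point where counts were pooled. An effect of the number of sites is therefore not excluded. Peak width, which rose with fold, was not matched, and neither was the number of peaks per gene. A gene's value is that of its strongest peak, so a gene with several peaks has more chances of a high fold. PAL1, PAL4 and CYP98A3 had 2 peaks each and PAL2 3, and the other genes of the list with a peak had 1. Among all 4030 nuclear genes with a peak, 3665 had 1. Width, the number of peaks per gene, the arrangement of sites and base composition stay open as candidate explanations, and no biological one was tested.

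Whether MYB67 peaks favour suberin enzymes and transporters over the MYB and NAC regulators of suberin was left undecided by 10 of 21 against 3 of 17 genes (odds ratio 4.08, 95% interval 0.789 to 28.8, Fisher's exact test, p = 0.08626). A preference for suberin over flavonoid genes was not detected (odds ratio 0.911, 95% interval 0.234 to 3.53, Fisher's exact test, p = 1), and the interval allows a difference in either direction. Phenylpropanoid genes had a higher median fold than suberin genes, 7.68 against 4.90 (permutation p = 0.0229, unadjusted), and more sites per strongest peak, 5.46 against 2.7 (permutation p = 0.0313, unadjusted). These peaks were also wider, with a median of 352 bp against 278 bp, and per 100 bp they held 1.25 sites against 0.847 (permutation p = 0.0451, unadjusted).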
